A study of Arabidopsis thaliana with 16 samples.

How the data were processed

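RNA from whole Arabidopsis thaliana seedlings, 7 days old, was measured on 16 Affymetrix ATH1 arrays. The seedlings had the ubp1c-1 allele and expressed a FLAG-tagged UBP1C under the 35S promoter. UBP1C is an RNA-binding protein. For each condition, RNA recovered with an anti-FLAG antibody (IP RNA) and total RNA from an aliquot of the cleared extract were labelled from their 3 prime ends, from 15 ng of IP RNA and 150 ng of total RNA. The conditions were light, 2 h of near darkness in air, 2 h of hypoxia in the dark under argon, and 2 h of hypoxia followed by 20 min of reoxygenation. This gave 8 groups of 2 arrays.

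The deposited values are log2 signals, a unit read from their range because the labels do not name it. The authors' processing notes name MAS5 and limma without their roles or versions, and the normalization is not stated. Array medians and spreads differed between arrays, so the arrays had not been quantile normalized together. The values were used as deposited. For arrays, depth is not counted in reads, and the number of arrays limits the precision. In place of present calls, which the table does not hold, background was taken as the brightest of the 3 unspiked tryptophan control probe sets of each array, and a probe set was counted as above background when it exceeded that by 1 on the log2 scale. This margin was chosen after the data were seen.

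Samples were grouped by title and source name. For replicate 2 of hypoxia total RNA, the treatment tag reads mock dark while its title and source name read hypoxia. It was kept as hypoxia, and each count was recomputed without it.

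The table held 22810 probe sets, of which 64 were controls, and 22746 were tested. A model of the 8 group means was fitted to log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual degrees of freedom 8, prior 6.14), and p values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets within each contrast. A probe set passed when its adjusted p was under 0.05. Association was IP minus total RNA within a condition, and a change in association was the difference of 2 associations. Control probe sets for plant transcripts were fitted in the same model. With 2 arrays against 2, an exact permutation test cannot give a p under 0.333, and chance alone separates the arrays of 33.3% of probe sets, so calls rest on the spread that limma pools over groups. Tested on simulated data, with 100 probe sets changed at each of 2 log2 sizes, the model recovered 93 at a change of 2 and 34 at 1 for association in hypoxia. There were 6 false calls over both sizes. For the change in association from dark to hypoxia it recovered 68 and 7, with 3 false calls. Far fewer probe sets changed in the simulation than passed in these contrasts, so the recovered shares may not hold where many passed.

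Sets of probe sets were tested with camera in limma, with a correlation between probe sets preset at 0.01 and again with the correlation estimated. Each tested set was chosen on arrays that the tested contrast does not use. Medians per replicate pair arrays by replicate number, although the numbers alone do not establish that same-numbered arrays share an extract. To compare sets at equal abundance, 10000 random draws of probe sets were matched on total RNA level in bins 0.5 wide on the log2 scale. Ratios of 3 prime to 5 prime signal were compared between the 8 IP and 8 total RNA arrays with two-sided exact permutation tests (scipy 1.17.1, python 3.11.15), adjusted over the 6 plant transcripts and, separately, over the 4 bacterial poly(A) controls.

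Alternatives were quantile normalization over all arrays or within each kind of RNA, median scaling, a filter on the mean, an intensity trend with a robust prior, blocks for replicate number and for extract, a minimum log2 difference of 1, fits on the arrays of a contrast alone, and leaving out each array. Added after the data were seen were scaling to the hybridization spikes, a filter on background, a block for a batch seen in those spikes, probe sets with a plain suffix, an estimated correlation for the sets, set tests among probe sets above background on both total RNA arrays of light, also against 1000 draws matched on level, and limma on the ratios of the 6 plant controls. The files used do not pair probe sets with genes. For that reason the gene lists, the FLAG-UBP1C transgene check, the tissue markers, the uridine content of 3 prime UTRs and the choice of named genes by gene were not analysed here. A rule fixed before the data were examined named, per contrast, the 5 probe sets with the largest positive and the 5 with the largest negative log2 difference among those that passed and did not overlap between groups. From these, 4 are printed by their identifiers, chosen after their values were seen, and the plant transcripts with control probe sets are named by the control.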

Results

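RNA bound to FLAG-UBP1C and total RNA were measured in seedlings kept in light, in the dark, under hypoxia and after reoxygenation, with 2 arrays per group. IP arrays had a median signal of 4.24 ± 0.29 on the log2 scale (SD, n = 8), and total RNA arrays one of 5.43 ± 0.18 (SD, n = 8). On IP arrays 11979 ± 878 probe sets lay above background, and on total RNA arrays 15120 ± 528 did (SD, n = 8 each). Replicate arrays correlated across probe sets, which are not independent replicates, with Pearson coefficients between 0.974 and 0.992. For 1 array, replicate 2 of hypoxia total RNA, the labels disagree on the treatment, and it was kept as hypoxia. Probe sets chosen for a rise of at least 1 from dark to hypoxia in total RNA of replicate 1 rose by a median of 1.51 in replicate 2, which argues against the mock dark tag.

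The first comparison asked which transcripts UBP1C held in each condition. In light, 1131 probe sets were higher in IP than in total RNA and 10986 were lower. In the dark 1045 were higher and 11415 lower, and after reoxygenation 1011 were higher and 10747 lower. Under hypoxia 1497 were higher and 6580 lower. Single arrays moved the higher counts: the 1131 in light became 1759 without replicate 1 of light IP RNA and 698 without replicate 2. The 1497 under hypoxia became 945 without replicate 2 of hypoxia IP RNA and 986 without replicate 2 of hypoxia total RNA, and the 1011 became 655 without replicate 2 of reoxygenation IP RNA. The median of all probe sets was -0.57 in light, -0.64 in the dark, -0.12 under hypoxia and -0.53 after reoxygenation on the log2 scale, and a different scaling of the arrays moved it. With each array centred on its median, the median of all probe sets became 0.82 in light and 0.40 under hypoxia, with 12833 higher and 5546 lower in light, 13068 and 5371 in the dark, 10431 and 4470 under hypoxia, and 12820 and 5308 after reoxygenation. With quantile normalization over all arrays the splits were 6695 higher and 5676 lower in light, 6630 and 5678 in the dark, 3656 and 3708 under hypoxia, and 5970 and 5278 after reoxygenation. Quantile normalization within each kind of RNA gave 12936 higher and 5506 lower in light, 12865 and 5507 in the dark, 11868 and 4560 under hypoxia, and 12791 and 5309 after reoxygenation. Scaling to the hybridization spikes left few enriched probe sets, with 73 higher and 10474 lower in light, 127 and 9685 in the dark, 81 and 2418 under hypoxia, and 56 and 10023 after reoxygenation. The share of transcripts called bound therefore depended on the scaling, while the order of transcripts within an array did not.

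Named transcripts differed in their association. Actin mRNA, a cytoskeletal transcript, was higher in IP RNA at its 3 prime probe set by 1.23 in light (SE 0.20, n = 2 per group, limma adjusted p = 9.39e-05) and by 1.34 under hypoxia (SE 0.20, n = 2 per group, limma adjusted p = 0.000106), calls that ended with spike scaling (0.39 and 0.99). At its 5 prime probe set it was lower in light, by -2.98 (SE 0.69, n = 2 per group, limma adjusted p = 0.00177), and under hypoxia it had -1.05 (limma adjusted p = 0.288), while the older 5 prime control had 1.07 in light (limma adjusted p = 0.00106), so the direction depended on the probe set. The lower 5 prime value in light, where 1 of 2 IP arrays was above background, was a call that ended with quantile normalization (-1.59, limma adjusted p = 0.0973). The middle probe set had -0.97 in light (limma adjusted p = 0.196). Ubiquitin mRNA was lower at its 3 prime probe set, by -1.28 in light (SE 0.22, n = 2 per group, limma adjusted p = 0.000132) and -0.67 under hypoxia (limma adjusted p = 0.0275). Its sign in light turned positive with median scaling (0.11), and with quantile normalization within each kind of RNA the sign turned in light (0.14) and under hypoxia (0.24). The 25S ribosomal RNA was the most depleted of the control transcripts, with an association of -4.60 in light, -5.09 in the dark, -3.80 under hypoxia and -4.39 after reoxygenation (SE 0.22 each, n = 2 per group). For GAPDH, a glycolytic enzyme, 2 generations of 3 prime control probe sets disagreed, at 0.17 and 1.14 in light. Probe set 257054_at, which the files do not pair with a gene, had a signal of 4.06 ± 0.55 in light IP RNA, where 1 of 2 arrays was above background, and of 11.54 ± 0.17 in light total RNA (SD, n = 2).

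The order of transcripts in IP RNA came closest to that in total RNA under hypoxia. The Spearman correlation between IP and total RNA, across probe sets, was 0.803 ± 0.0028 in light, 0.811 ± 0.0046 in the dark, 0.930 ± 0.0047 under hypoxia and 0.849 ± 0.015 after reoxygenation (SD, n = 2 each). Both hypoxia values lay above all values of the other conditions, although 2 values against 2 cannot give an exact p under 0.333. Scaling of whole arrays leaves these values as they are. Among probe sets above the median of the mean over all 16 arrays they were 0.426, 0.445, 0.733 and 0.534 in the same order. This filter can keep probe sets near background on IP arrays. Hypoxia IP arrays had 13263.5 ± 158 probe sets above background, beside 11609 ± 540 in light, 11203 ± 495 in the dark and 11840.5 ± 152 after reoxygenation (SD, n = 2 each). How far this raised the hypoxia correlation was not tested.

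**Figure D1:**
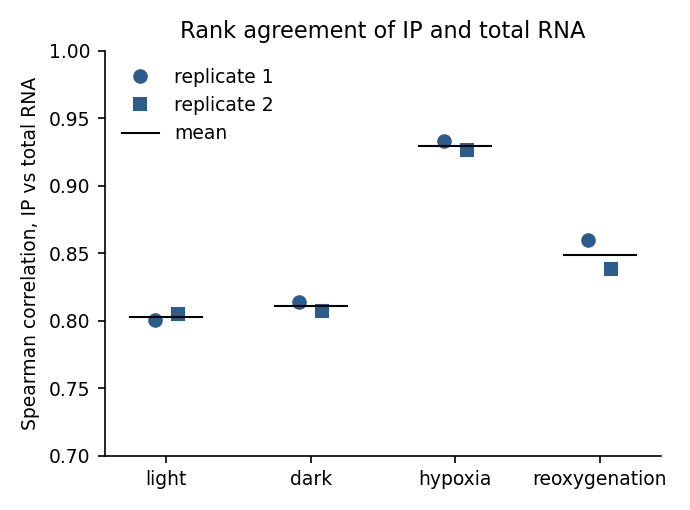
Spearman correlation across probe sets between IP and total RNA arrays of the same condition and replicate number, with the vertical axis drawn from 0.7 to 1. Circles and squares are the 2 replicates and lines their means, which were 0.930 under hypoxia and at most 0.849 in the other conditions.

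The second comparison asked how association changed when oxygen was withdrawn. From dark to hypoxia, association rose for 6624 probe sets and fell for 33, against a median change of all probe sets of 0.51. The transcripts depleted in light account for most of the rise: 6302 of 10986, or 57.4%, rose, and their median association went from -2.04 ± 0.19 in the dark to -0.88 ± 0.15 under hypoxia (SD, n = 2). Their IP signal rose by a median of 0.87 ± 0.04 while their total RNA changed by -0.20 ± 0.02 (SD, n = 2), and with median scaling these were 0.26 and 0.20. On the same IP arrays, the 3 prime minus 5 prime difference was 8.32 ± 0.30 in the dark and 5.77 ± 1.56 under hypoxia for actin (SD, n = 2), and 7.28 and 4.50 for the older GAPDH controls. The other controls moved by less, from 2.94 to 1.77 for newer GAPDH and from 1.77 to 1.49 for newer ubiquitin. Older actin went from 6.26 to 5.96 and older ubiquitin from 3.35 to 3.18. Among the 1131 transcripts enriched in light, 9 rose and 11 fell, with a median association of 1.02 and 1.18 in the replicates of the dark and of 0.98 and 1.29 in those of hypoxia. Relative to other probe sets, the depleted set shifted up (camera adjusted p = 3.25e-79, and adjusted p = 0.00925 with an estimated correlation). Most of the others had too little signal to change, the 10629 not called in light having medians of 3.53 in IP and 3.62 in total RNA of the dark. Among the 15017 probe sets above background in light total RNA, the depleted set had a median change of 1.17 beside 0.35 for the 4341 others (camera adjusted p = 3.98e-49, and adjusted p = 0.0328 with an estimated correlation), and at equal total RNA level in light it lay 0.84 ± 0.14 higher (SD, n = 2). The enriched set shifted down relative to all others (camera adjusted p = 3.18e-23), a call lost with an estimated correlation (adjusted p = 0.148) but not among the 15017 (adjusted p = 0.0328 with an estimated correlation). Its own median change was 0.0026. Among the 15017, 10676 of its 14108 others were the depleted set, so this call mainly restates the rise of that set. The split of 6624 and 33 became 1650 higher and 1302 lower with quantile normalization, 1710 and 1223 with quantile normalization within each kind of RNA, and 2117 and 8504 with median scaling, where the median of all probe sets was -0.49. With spike scaling 138 were higher and 0 lower. The spikes of replicate arrays differed by more than the array medians did (SD 0.87 beside 0.21 for dark IP RNA, n = 2). Part of this drop therefore reflects a wider spread within groups. The difference between the depleted set and the other probe sets, 1.01 in the median, kept its sign, at 0.49 with quantile normalization and 0.43 within each kind of RNA.

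**Figure D2:**
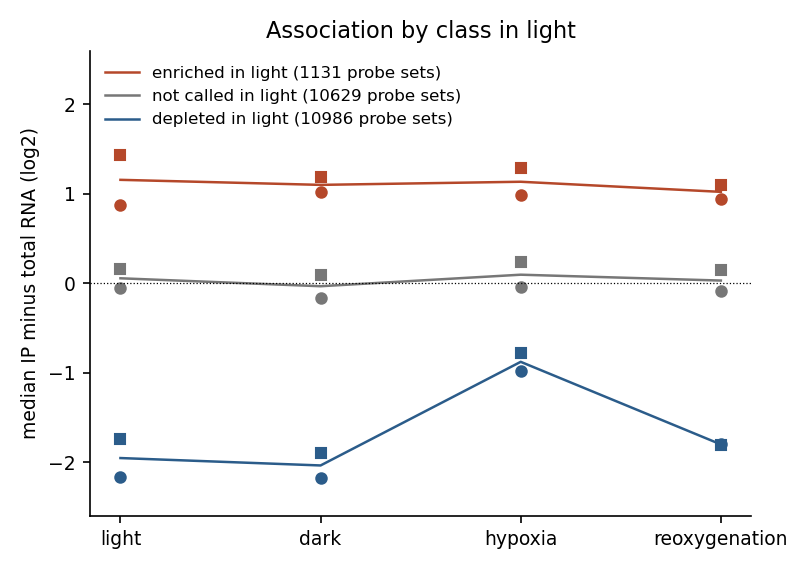
Median IP minus total RNA on the log2 scale by condition, for probe sets enriched, depleted or not called in light, with circles and squares for the 2 replicates and lines through their means. The classes were chosen on the light arrays, so the light values are not independent of the choice; the depleted class lay at -2.04 in the dark and -0.88 under hypoxia.

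Named transcripts moved by different amounts. The association of 25S ribosomal RNA rose by 1.29 from dark to hypoxia (SE 0.31, n = 2 per group, limma adjusted p = 0.00605) as deposited, a call that ended under each other scaling. The change was 0.29 with median scaling, 0.41 with quantile normalization, 0.58 within each kind of RNA and 1.56 with spike scaling (limma adjusted p = 0.396, 0.423, 0.256 and 0.552). The 3 prime probe set of actin changed by 0.05 (limma adjusted p = 0.95) as deposited and by -0.95 with median scaling. That of ubiquitin changed by 0.74 (limma adjusted p = 0.093) as deposited, which did not pass in the fit without a replicate block, and its sign turned negative with median scaling. For GAPDH of the older controls, the 3 prime probe set changed by -0.24 (limma adjusted p = 0.652), and that of the newer controls by 0.68 (limma adjusted p = 0.0727, or 0.048 with replicate number as a block) as deposited and by -0.32 with median scaling. The older 5 prime probe set rose by 1.88 (SE 0.64, limma adjusted p = 0.0383) as deposited. It changed by 0.88, 0.64, 0.96 and 2.15 under the same 4 scalings (limma adjusted p = 0.19, 0.494, 0.292 and 0.333), which did not pass. With 1 array left out it passed without replicate 2 of dark IP RNA or replicate 1 of hypoxia IP RNA, and did not pass without any 1 of the other 6 arrays. Probe set 257054_at rose in association by 4.89 (SE 0.49, limma adjusted p = 1.26e-05), reaching 9.33 ± 0.61 in IP RNA beside 11.91 ± 0.22 in total RNA (SD, n = 2). Its dark IP signal, 4.17 ± 0.43 (SD, n = 2), was above background on 1 of 2 arrays, so the size of this change depends on the background. The hybridization spikes of replicate 1 of dark and of hypoxia were brighter than those of the other arrays. Within that batch the depleted set rose by 1.18, and in replicate 2 it rose by 1.14.

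With reoxygenation, association fell again. This fall and the rise from dark to hypoxia share the hypoxia arrays, including replicate 2 of total RNA, whose labels disagree, so they are not independent findings. From hypoxia to 20 min of reoxygenation association rose for 5 probe sets and fell for 4459, against a median change of all of -0.44. The split was 173 higher and 502 lower with quantile normalization, 188 and 597 within each kind of RNA, 5844 and 1393 with median scaling, and 0 and 22 with spike scaling. Of the transcripts depleted in light, 4210 fell, and their median association returned to -1.80 ± 0.01 (SD, n = 2). On the IP arrays the 3 prime minus 5 prime difference went from 5.77 ± 1.56 to 7.11 ± 0.79 for actin (SD, n = 2) and from 4.50 to 6.11 for the older GAPDH controls. The other controls moved by less, from 1.77 to 2.28 for newer GAPDH, from 5.96 to 6.40 for older actin and from 3.18 to 3.47 for older ubiquitin. Newer ubiquitin went the other way, from 1.49 to 1.33. The set shifted down relative to other probe sets, most of them near background (camera adjusted p = 8.57e-66, and adjusted p = 0.0122 with an estimated correlation). Among the 15017 above background in light total RNA it had a median change of -0.93 beside -0.35 for the others (camera adjusted p = 5.5e-37, and adjusted p = 0.0426 with an estimated correlation), and at equal level it lay -0.59 ± 0.02 from them (SD, n = 2). The enriched set shifted up relative to all others (camera adjusted p = 3.35e-14, and adjusted p = 0.246 with an estimated correlation, or 0.0445 among the 15017). Its own median change was -0.077, so this call mainly restates the fall of the depleted set. Probe set 257054_at fell in association by 3.94 (SE 0.49, limma adjusted p = 0.000164). After reoxygenation association was higher than in the dark for 77 probe sets and lower for 118. All 118 were among the 773 probe sets higher in total RNA after reoxygenation than in light, and 102 were among the 352 that rose from hypoxia to reoxygenation. Their lower association therefore came with a rise in total RNA that IP RNA did not match. The majority direction was not stable, with 257 higher and 196 lower when replicate number was a block, and 156 and 166 when the extract was. Without replicate 1 of dark total RNA these were 12 and 79. Without replicate 2 of dark total RNA, replicate 1 of reoxygenation IP RNA, or replicate 1 or 2 of reoxygenation total RNA, 110, 120, 112 and 108 passed in all. The split was 55 higher and 216 lower with median scaling, and 0 and 22 with spike scaling. Without replicate 2 of hypoxia total RNA, the count for hypoxia to reoxygenation was 1 higher and 2904 lower, and without replicate 2 of reoxygenation total RNA it was 2 and 2585.

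Few differences between dark and light passed. Association differed between dark and light for 1 probe set by limma, which was lower, with 553 at an unadjusted p under 0.05. That call ended with quantile normalization, with spike scaling and with a block for the hybridization batch. Without replicate 1 of light IP RNA 3 passed, and 0 did without replicate 2 of light IP or total RNA, replicate 1 of dark IP RNA, or either array of dark total RNA. In total RNA, 12 probe sets were higher in the dark and 9 lower, with 820 at an unadjusted p under 0.05. Both 553 and 820 lie below what chance alone gives among 22746 probe sets. In simulated data 7 of 100 changes of 1 in association from dark to hypoxia were recovered, so smaller changes with darkness could be missed. The split was 24 higher and 29 lower with replicate number as a block, 8 and 4 with quantile normalization, and 7 and 3 among probe sets above the median mean, and with spike scaling 0 passed. Without replicate 1 of dark total RNA, 3 passed, and without replicate 2 of dark total RNA or of light total RNA, 6 and 8 passed.

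The third comparison asked how total RNA itself responded. From dark to hypoxia 339 probe sets rose and 1386 fell in total RNA. The split was 401 higher and 428 lower with quantile normalization, 650 and 710 within each kind of RNA, 2239 and 529 with median scaling, and 29 and 2 with spike scaling. With replicate number as a block 498 rose and 2414 fell. Without replicate 2 of hypoxia total RNA, the array whose labels disagree, 129 rose and 194 fell. Without replicate 1 of hypoxia total RNA, 214 rose and 714 fell, and without replicate 1 or replicate 2 of dark total RNA, 407 and 732 passed. Probe set 262382_at rose from 4.24 ± 0.08 to 8.64 ± 0.35 (SD, n = 2), by 4.41 (SE 0.37, limma adjusted p = 1.49e-05). Probe set 260209_at fell from 8.09 ± 0.12 to 4.81 ± 0.48 (SD, n = 2), by -3.28 (SE 0.24, limma adjusted p = 6.19e-06). From hypoxia to reoxygenation 352 rose and 15 fell in total RNA, which became 259 and 57 with median scaling and 148 and 0 with spike scaling. With replicate number as a block 535 rose and 22 fell, and among probe sets above the median mean 177 and 5 did. Without replicate 1 of hypoxia total RNA 221 passed, and without replicate 1 or 2 of reoxygenation total RNA 239 and 235 did. Probe set 250351_at rose from 4.32 ± 0.28, with 1 of 2 arrays above background, to 10.19 ± 0.10 (SD, n = 2), by 5.86 (SE 0.28, limma adjusted p = 1.19e-08).

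As deposited, transcripts that changed in total RNA behaved in different ways in IP RNA, a contrast that depended on the scaling. The 339 that rose under hypoxia rose by a median of 1.44 ± 0.06 in total RNA and 1.64 ± 0.11 in IP RNA (SD, n = 2), while the median over probe sets of their change in association was 0.04 ± 0.13. Of them 46 rose and 22 fell in association. The 1386 that fell under hypoxia changed by -1.04 ± 0.06 in total RNA and by 0.19 ± 0.02 in IP RNA (SD, n = 2). Of them 972, or 70.1%, rose in association, beside 29.1% of all probe sets. The 352 that rose on reoxygenation rose by 1.68 ± 0.05 in total RNA and changed by 0.11 ± 0.12 in IP RNA (SD, n = 2). Of these, 267, or 75.9%, fell in association, beside 19.6% of all probe sets. The IP changes depended on the scaling. With median scaling IP RNA of the 3 sets changed by 1.04, -0.41 and 0.63 beside 1.84, -0.64 and 1.41 in total RNA, with quantile normalization by 0.95, -0.49 and 0.67 beside 1.56, -0.64 and 1.31, and within each kind of RNA by 0.84, -0.36 and 0.57 beside 1.65, -0.75 and 1.49. Under these scalings IP RNA of all 3 sets moved in the direction of total RNA and by less. IP RNA of the 1386 fell, and that of the 339 and of the 352 rose. With spike scaling IP RNA of the 3 sets changed by 1.92, 0.47 and 0.25. These sets were chosen on the total RNA arrays that also enter the association, so a choice by chance error moves the association the other way. A true change in total RNA does so too where IP RNA stays flat, so the shares that moved in association are no separate evidence. Probe set 250351_at was not above background in IP RNA of any group, at 3.56 ± 0.09 after reoxygenation (SD, n = 2). Probe set 262382_at was not above background in dark IP RNA and had 4.99 ± 0.38 under hypoxia (SD, n = 2).

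**Figure D3:**
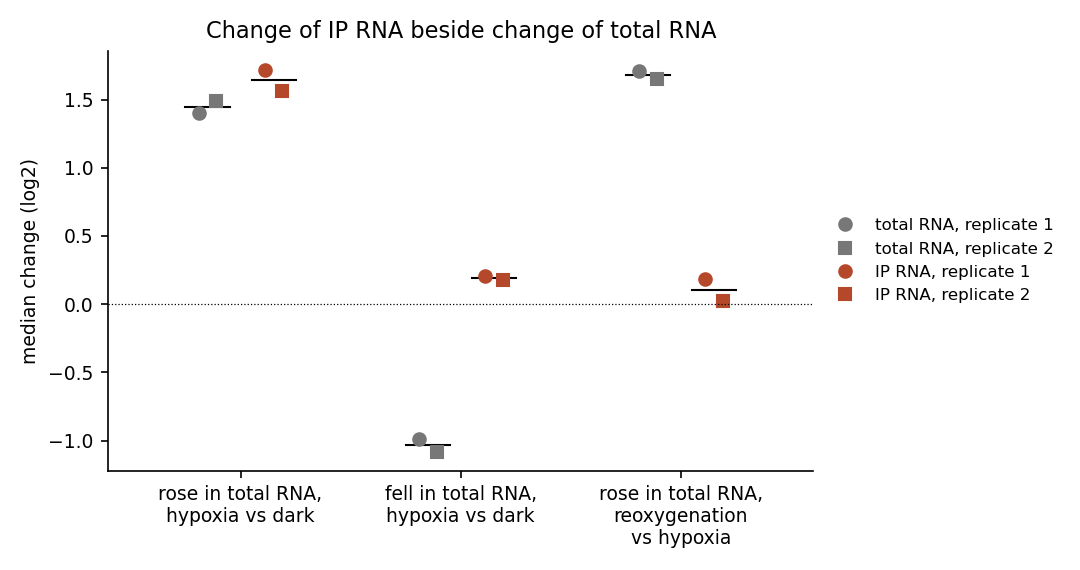
Median log2 change in total RNA (grey) and IP RNA (red) of the probe sets that changed in total RNA, with circles and squares for the 2 replicates and lines for their means. Probe sets that rose on reoxygenation rose by 1.68 in total RNA and changed by 0.11 in IP RNA as deposited, or 0.63 with median scaling, where the IP change of those that fell under hypoxia turned to -0.41; the total RNA values are those the sets were chosen on.

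The difference between 3 prime and 5 prime signal was larger in IP RNA than in total RNA. The 3 prime probe set of actin exceeded the 5 prime one by 7.40 ± 1.39 on IP arrays and 3.87 ± 0.41 on total RNA arrays (log2, SD, n = 8 each), and all 8 IP arrays lay above the highest total RNA array (two-sided exact permutation p = 0.000155, the smallest possible, adjusted p = 0.000233 over 6 tests). For GAPDH the difference was 2.64 ± 0.98 and 0.94 ± 0.30, with 7 of 8 IP arrays above the highest total RNA array (exact permutation p = 0.000311, adjusted p = 0.000373). For ubiquitin it was 1.56 ± 0.35 and 1.17 ± 0.17, with 6 of 8 above (exact permutation p = 0.0141, adjusted p = 0.0141). The older controls gave 0.74 more for actin, 3.71 for GAPDH and 1.36 for ubiquitin on IP arrays, each with 8 of 8 above (exact permutation adjusted p = 0.000233). Among IP arrays, the difference for actin was 5.77 ± 1.56 under hypoxia and 8.32 ± 0.30 in the dark (SD, n = 2), while that for ubiquitin was 1.49 and 1.77.

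**Figure D4:**
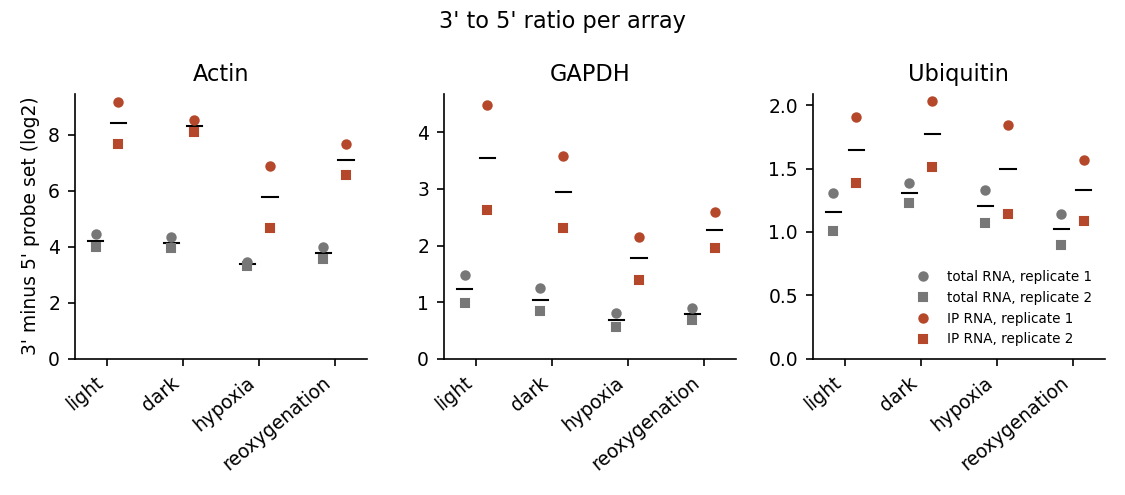
Log2 signal of the 3 prime minus the 5 prime control probe set for actin, GAPDH and ubiquitin on each array, by condition, with grey for total RNA, red for IP RNA and lines for the means of 2 replicates. For actin all 8 IP arrays lay above the 8 total RNA arrays.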

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

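All tests of explanations in this part were chosen after the results were seen. So were the set tests among probe sets above background in light total RNA. The tests of changes in association themselves were planned.

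Association changes that passed a test of the difference between conditions drew attention as follows. Association differed between dark and light for 1 probe set, between hypoxia and dark for 6657, between reoxygenation and hypoxia for 4464 and between reoxygenation and dark for 195. The association of 25S ribosomal RNA was 1.29 higher under hypoxia than in the dark, and that of the older GAPDH 5 prime probe set 1.88 higher. With median scaling these were 0.29 and 0.88, and with spike scaling, which widened the SE to 0.99, 1.56 and 2.15. Neither call held under any of the other 4 scalings. For 262382_at, association changed by -2.39 from dark to hypoxia and by -3.23 from dark to reoxygenation, with IP signal not above background in the dark and after reoxygenation, so association there was not measured. For 250351_at the fitted values were -5.51 from hypoxia to reoxygenation and -6.15 from dark to reoxygenation. Its IP signal was above background on no array, and its total RNA on 0 of 2 arrays in the dark and 1 of 2 under hypoxia, so these values restate its rise in total RNA and a change in association was not determined. For 257054_at it changed by 4.89 from dark to hypoxia and by -3.94 from hypoxia to reoxygenation, with 1 of 2 dark IP arrays above background.

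Whole sets also differed from other probe sets between conditions, by camera with a preset correlation. The median of the fitted changes of the 1131 transcripts enriched in light was 0.0026 from dark to hypoxia, -0.077 from hypoxia to reoxygenation and -0.081 from dark to reoxygenation. For the 10986 depleted in light it was 1.15, -0.91 and 0.26 in the same order. The 773 transcripts higher in total RNA after reoxygenation than in light had a median change of 0.28 from dark to hypoxia, below that of other probe sets, and the 566 that were lower one of 1.23, above it. With an estimated correlation, the calls for the depleted set from dark to hypoxia (adjusted p = 0.00925) and from hypoxia to reoxygenation (adjusted p = 0.0122) held. The calls for the enriched set (adjusted p = 0.148, 0.246 and 0.346), for the depleted set from dark to reoxygenation (adjusted p = 0.346) and for the 773 and 566 transcripts (adjusted p = 0.346 and 0.148) did not. Most other probe sets were near background, and among the 15017 above it in light total RNA, with an estimated correlation, the depleted set (adjusted p = 0.0328 and 0.0426) and the enriched set (adjusted p = 0.0328 and 0.0445) passed from dark to hypoxia and from hypoxia to reoxygenation. For the enriched set, 10676 of the 14108 others were the depleted set, so its calls mainly restate the change of that set.

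IP RNA ranked more like total RNA under hypoxia than in the dark. Scaling of whole arrays cannot move a rank correlation, which differed by 0.119. Carry-over of unselected extract would bring every RNA at 1 ratio, yet the transcripts depleted in light lay 2.92 ± 0.06 (SD, n = 2) above 25S ribosomal RNA in association under hypoxia. A gap was there before hypoxia too, with 25S ribosomal RNA at -5.09 in the dark. From dark to hypoxia it rose by 1.29 as deposited, beside a median of 1.15 for the depleted set. The gap therefore speaks against carry-over of whole extract as the main source of the signal of that set, while a smaller part was not excluded. Less 3 prime bias in the hypoxia IP RNA stays open: its slope within conditions gave a change of -0.00736, but replicate 1 was the more biased array in all 4 conditions, so bias and replicate cannot be told apart. Carry-over of mRNA complexes free of ribosomal RNA stays open too, because no mock immunoprecipitation is among the arrays, and so does binding of UBP1C to a wider range of mRNAs when oxygen was lacking.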

How the results depend on the processing

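Of the alternatives reported here, spike scaling, the background filter, the plain suffix, the hybridization batch block, the estimated correlation, the set tests above background and the settings of rank correlations, set medians and set changes were chosen after the data were seen. Total association counts in each condition stayed within 1.5 times under the filters, blocks, priors and left-out arrays, but not under every scaling, and the counts higher in IP RNA moved by more when single arrays were left out. Leaving out arrays, with the lone array assumed to vary like other groups, gave association counts of 10828 to 12300 in light, 11132 to 12214 in the dark, 6216 to 7222 under hypoxia and 10278 to 10999 after reoxygenation. It gave 3 to 16 for total RNA dark against light, 323 to 928 for hypoxia against dark and 221 to 253 for reoxygenation against hypoxia. For changes in association it gave 0 to 3 for dark against light, 4843 to 6865 for hypoxia against dark, 2587 to 4447 for reoxygenation against hypoxia and 91 to 150 for reoxygenation against dark. Rank correlations ranged from 0.801 to 0.805, 0.807 to 0.814, 0.926 to 0.933 and 0.838 to 0.860 in light, dark, hypoxia and reoxygenation. The cause was not tested unless given.

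With quantile normalization, total RNA counts were 12 for dark against light and 829 for hypoxia against dark, and association changes 0 for dark against light, 2952 for hypoxia against dark and 675 for reoxygenation against hypoxia. Within each kind of RNA, association counts were 18442 in light, 16428 under hypoxia and 18100 after reoxygenation, and changes 0, 2933, 785 and, for reoxygenation against dark, 303. Median scaling gave association counts of 18379, 14901 and 18128 in light, hypoxia and reoxygenation, 2768 for total RNA hypoxia against dark, and changes of 10621 for hypoxia against dark and 7237 for reoxygenation against hypoxia. Spike scaling gave 2499 for association under hypoxia, total RNA counts of 0, 31 and 148, and changes of 0 for dark against light, 138 for hypoxia against dark, and 22 each for reoxygenation against hypoxia and against dark. These scalings move whole arrays by construction.

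Restricted to probe sets above the median mean, with fewer probe sets, total RNA counts were 10, 1051 and 182, the change for reoxygenation against dark 46, and rank correlations 0.426, 0.445, 0.733 and 0.534 in light, dark, hypoxia and reoxygenation. The replicate block gave 53, 2912 and 557 for total RNA and 453 for the change from dark to reoxygenation, where deviations of same-numbered arrays correlated by a median of 0.287 over 28 pairs of groups. The extract replicate block gave 322 for that change. The hybridization batch block gave 0 for the change from light to dark. A minimum log2 difference of 1 gave 1024 for total RNA hypoxia against dark. Fits on the arrays of the contrast alone gave 3156 for it, and changes of 0 for dark against light and 302 for reoxygenation against dark.

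The median of the depleted set minus the others changed from 1.01 to 0.49 with quantile normalization and 0.43 within each kind of RNA for hypoxia against dark, and from -0.81 to -0.33 and -0.28 for reoxygenation against hypoxia. For single features, 1097 of 1210 values were the same, 63 weaker, 38 stronger and 12 reversed. A value was reversed when its sign turned and it passed in the main fit or the alternative. A value that passed in neither could turn sign and still count as the same, as the change of the newer GAPDH 3 prime probe set did with median scaling. With median scaling the reversed values were actin 3 prime changes of -0.95 and 0.75, ubiquitin association of 0.11 in light and 0.12 in the dark, 0.25 for 262382_at in the dark, and 1.16 and 1.05 for 250351_at in light and dark. Within each kind of RNA they were ubiquitin 0.14 in light and 0.24 under hypoxia, 0.024 for 262382_at in the dark, and 0.97 and 0.78 for 250351_at in light and dark. The floor of 64 does not apply to log2 values. Probe sets of exactly 1 gene, gene list shifts, named genes and uridine content were not run, since the files used do not pair probe sets with genes. Signal over background limits dim probe sets, 15889 being above it on both arrays of at least 1 group.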

Other observations

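All tests of explanations in this part were chosen after the results were seen, as were the matched draws, and the explanation by RNA cutting and the bounds of its test were revised after its value was known.

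Association was largely shared between conditions. Of the 1131 probe sets enriched in light, 857 were enriched in the dark, 840 under hypoxia and 780 after reoxygenation, where independent choice would give 52.0, 74.4 and 50.3. Independent choice is a low reference, since dim probe sets can hardly be called and IP and total RNA arrays differed in RNA input in every condition. The excess over it therefore does not test shared binding. In all 4 conditions 673 probe sets were enriched and 6390 depleted. Of the 10986 depleted in light, 10531 were depleted in the dark, 6433 under hypoxia and 9922 after reoxygenation. Transcripts of total RNA signal 8 to 10 in light, 3022 probe sets, had a median association of -2.43 in light, -2.38 in the dark, -0.87 under hypoxia and -2.01 after reoxygenation. The dimmest 7004 probe sets had 0.12, 0.0087, 0.066 and 0.076, where signal near background limits any difference.

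Compared with transcripts of equal total RNA level, the 773 that were higher in total RNA after reoxygenation than in light had a median association under hypoxia of -0.75 beside -0.56 for matched draws. That set was chosen on arrays that the association under hypoxia does not use. The difference was -0.10 in replicate 1, where 71 of 10000 draws were as low, and -0.24 in replicate 2, where 0 were. Its mean, -0.17 ± 0.094 (SD, n = 2), was less than 2 SD from 0, and probe sets are not replicates, so a difference was not established.

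Transcripts that rose in total RNA during reoxygenation rose less in IP RNA, and by how much less depended on the scaling. With the set chosen on 1 replicate and measured on the other, total RNA rose by 1.35 ± 0.13 and IP RNA changed by -0.0003 ± 0.029 as deposited (-1.43% and 1.59% of the rise in the 2 replicates, a mean of 0.084%), while with median scaling total RNA rose by 1.07 ± 0.03 and IP RNA by 0.52 ± 0.00027 (SD, n = 2 each). At equal total RNA level, association of the set lay -0.25 ± 0.14 (SD, n = 2) from that of other transcripts, less than 2 SD, so the level as a cause cannot be told apart from a difference of the set itself. Transcripts that rose during 2 h of hypoxia rose in IP RNA by 1.61 ± 0.11 beside 1.41 ± 0.15 in total RNA as deposited, but by 1.01 ± 0.05 beside 1.80 ± 0.16 with median scaling (SD, n = 2 each). Whether 20 min is too short to bind UBP1C stays open, since scaling sets the size of this contrast and time and oxygen supply changed together, so that their effects cannot be told apart.

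The 3 prime to 5 prime ratio of plant transcripts was larger in IP RNA. Incomplete labelling of the smaller amount of RNA would raise the ratio of the bacterial poly(A) controls too, which differed by a mean of -0.14 between IP and total RNA (-0.45 to 0.21 over 4 controls, exact permutation adjusted p = 0.17, 0.242, 0.17 and 0.725). This speaks against labelling if the controls were added before it in proportion to the RNA. The ratio in IP RNA was lower under hypoxia than in the dark for all 6 controls, as it was in total RNA (actin by -0.76), and by more than 2 SD of the replicates for actin (-2.55, SD 1.12) and the older GAPDH controls (-2.78, SD 0.85). By limma over the 4 conditions 0 of 6 passed (lowest adjusted p = 0.0534, with 2 at an unadjusted p under 0.05). With replicate number as a block actin and both GAPDH controls did (limma adjusted p = 0.00877, 0.0416 and 0.0078). Same-numbered arrays deviated together across probe sets in all 28 pairs of groups (correlations of 0.108 to 0.484), which favours the block, although the labels do not say that equal numbers mark pairs. With total RNA subtracted, 2 of 6 passed with the block (lowest limma adjusted p = 0.0231) and 0 without it. Most controls thus did not pass, and equal cutting in every immunoprecipitation cannot be told apart from cutting that differs between conditions or binding of shortened transcripts.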
